A study of Mus musculus with 12 samples.

How the data were processed

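Total RNA had been extracted with Trizol from bone of female C57BL/6 mice that underwent a sham operation or bilateral ovariectomy at 12 weeks of age, per the labels. Exercised mice ran on a treadmill for 9 weeks, per the labels. Each of 12 samples was labelled with Cy3 and hybridised to its own single-colour Agilent array, which gave 4 groups of 3 arrays: sham, sham with exercise, ovariectomized, and ovariectomized with exercise. Groups and replicate numbers were taken from the labels. The labels do not say that the 3 samples of a group came from separate animals, so p-values measure the spread between these samples, part of which may be technical.

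The deposited scanner files hold spot intensity on a linear scale. Per the file headers, the intensity used here is the processed signal of Agilent Feature Extraction 11.5.1.1, from which background had been subtracted and a spatial trend removed, with a grid built on mm9. The submitters' processing notes name Feature Extraction 10.7, and the difference between the versions was left as it is. The deposited table of the whole series holds log2 values. Set against the scanner values of each array it had a slope of 1 and a correlation of 1 over 97836 probes, and its 75th percentile lay near 0 in each column, so scale, centring and direction were all settled from the data. Its column medians were -2.08, -2.06 and -2.14 for ovariectomized exercised replicates 1 to 3, -2.17, -2.10 and -2.13 for ovariectomized, -2.12, -2.24 and -2.23 for sham exercised, and -2.07, -2.13 and -2.19 for sham. It served as an alternative.

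Of each array, 175906 spots remained after controls were left out. They belong to 97836 probes, 19766 with 1 spot and 78070 with 2. Over all arrays 171 outlier spots were left out, and no saturated spot was found. The log2 processed signal was averaged over the spots of a probe, and each array's 75th percentile was subtracted. Probes with a missing value, 21 in all, were left out. Probes well above background on at least 3 of the 12 arrays were tested, which left 80713. Of these 66191 were well above background on all 12 arrays. With arrays, the number of samples limits the precision.

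The files pair no probe with a gene name. RefSeq accessions, RIKEN clone names and RNA names in the probe IDs were matched, without versions, to a RefSeq gene table of assembly GRCm38.p6. This named 5891 probes of 5417 genes, 4656 of them among 13017 RefSeq non-coding transcripts and 1212 among 15675 RIKEN clones. All 39027 probes of Agilent's catalogue, 28773 NONCODE transcripts, 942 Ensembl transcripts and 373 ultraconserved elements stayed unnamed. Among the probes tested, 4293 had a name, for 4034 genes. By biotype most named probes, 4989, are long non-coding RNAs and 694 are transcripts of protein-coding genes. Because the grid and the gene table use different builds, no coordinates are given, and the table served only for names and for which genes lie next to each other. Some neighbouring genes are not reported here. A gene with several probes was represented by its brightest one. The probes of 1500009C09Rik and of Gm33861 gave different values. Probes of RIKEN clones and of RefSeq non-coding transcripts that carry the name of a protein-coding gene need not measure its coding transcript.

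A linear model with 4 group means was fitted with limma 3.58.1 in R 4.3.3, with the package data.table (version 1.17.8), and moderated by eBayes (8 residual and 2.91 prior degrees of freedom). Contrasts were the operation in non-exercised mice, the operation in exercised mice, exercise in ovariectomized mice, exercise in sham mice, the interaction, and both averaged effects. Set tests came from the same package. The p-values were adjusted by the Benjamini-Hochberg method within a contrast, at a threshold of 0.05, and all adjusted p-values of single probes in the text come from limma. The groups, tests, alternatives, 31 gene lists and the rule for naming genes were chosen before the data were examined. The rule took, for each simple comparison, up to 7 rises and 7 falls among named genes that passed and whose arrays did not overlap between groups, filled up to 5 a direction by the smallest unadjusted p where fewer passed. It further took up to 3 rises and 3 falls among non-coding probes, the 3 members with the smallest p of each list past camera, the 2 such members of 9 lists on bone, marrow and estrogen, and 15 single genes. For averaged and interaction contrasts it took up to 5 rises and 5 falls that passed, or 3 a direction by unadjusted p. A probe well above background on no array of a group has only a bound there. Its fold is then given as "at least", from the bright group's mean against the dim group's mean of, per array, the higher of the lowest signal among probes well above background and the probe's own signal. Where the probe's own signal is the higher on each array, this equals the measured fold. Such a bound concerns the background only and leaves out the SE. A probe may need a signal above the lowest of all such probes to be detected. The true fold may then be smaller, so "at least" is not a strict lower limit.

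Gene lists with at least 5 measured members were tested with camera at an inter-gene correlation of 0.01, with an estimated correlation and with fry. Of 662 list genes 24 were measured under their name: 20 lists had no measured member, 10 had 1 to 3, and the list of known long non-coding RNAs had 12. No list of osteoblast, osteocyte, osteoclast, Wnt, adipocyte, muscle or lymphocyte genes could be tested.

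Alternatives changed the normalization (quantile), the background correction (normexp with an offset of 50), the filter on dim probes, the source of the values, the weights, the moderation, the samples in the fit, the threshold and the block (replicate number or slide), and left out each array in turn. Normexp had been planned on the mean spot signal, a column not used here, and was run on the median spot signal. The scan coincides with the slide, so it was not fitted separately. Slides as a random block, the brightness of the spike-in controls as a block, and quantile normalization together with the slide block were chosen after seeing the data.

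The fit was tested on simulated data with the real probes' means and moderated spreads, with 100 probes changed by 2-fold and 100 by 4-fold in each comparison. The simulated noise was independent between probes and between arrays, with no slide, spike-in or brightness difference. The shares below therefore need not hold for the real arrays. At 4-fold it recovered 86% of the changed probes for the operation in non-exercised mice, 86% for the operation in exercised mice, 75% for exercise in ovariectomized mice, 88% for exercise in sham mice, 96% and 93% for the averaged operation and exercise effects, and 47% for the interaction. At 2-fold the shares were 31%, 29%, 26%, 29%, 74%, 68% and 0%, in the same order. A limit first set, 50% recovered at 4-fold, was missed by the interaction. It was then replaced by limits on the mean error (0.2 on the log2 scale) and on false calls (15% of calls), which each comparison met. In 1000 simulated sets of 12 unshifted, uncorrelated genes, camera passed 3.6% and fry 4.6% for the operation in non-exercised mice.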

Results

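Long non-coding RNAs, transcripts that are not translated, were measured in bone of mice after a sham operation or removal of both ovaries, an operation that lowers estrogen and leads to bone loss. The title of the series names the effect of exercise on these RNAs in osteoporotic bone as its subject. Exercised mice were familiarised with the treadmill at 6 m/min for 30 min in week 1, and from week 2 ran for 55 min at 8 m/min on a 25° slope after a 5 min warm-up. The speed then rose by 1 m/min a week to 15 m/min. Each of the 4 groups held 3 arrays. Between 71.0% (sham replicate 3) and 82.6% (ovariectomized exercised replicate 1) of probes were well above background, and arrays correlated at 0.940 to 0.989 across probes, which are not independent replicates. Sham exercised replicate 1 stood apart, with a median correlation of 0.951 to the others against at least 0.970 for each other array.

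The arrays lay on 3 slides of 4. Slide 1 held the ovariectomized exercised group and sham replicate 1, slide 2 the ovariectomized group and sham replicate 2, and slide 3 the sham exercised group and sham replicate 3. The labelled spike-in controls, RNAs of known sequence added to each sample, averaged 9.53 to 9.75 on the log2 scale on 5 arrays, all of ovariectomized mice. They averaged 8.51 to 9.00 on the other 7, which were ovariectomized replicate 3 and all sham arrays. The operation therefore nearly coincided with the brightness of these controls and partly with the slide, and the counts of probes are given with either as a block too. The spike-in block rests on ovariectomized replicate 3. Each non-exercised sham array had position 4 on its slide and the arrays of the other 3 groups positions 1 to 3, so a difference from that array within a slide, and the slide block, which links the groups through it, also coincide with position.

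**Figure D1:**
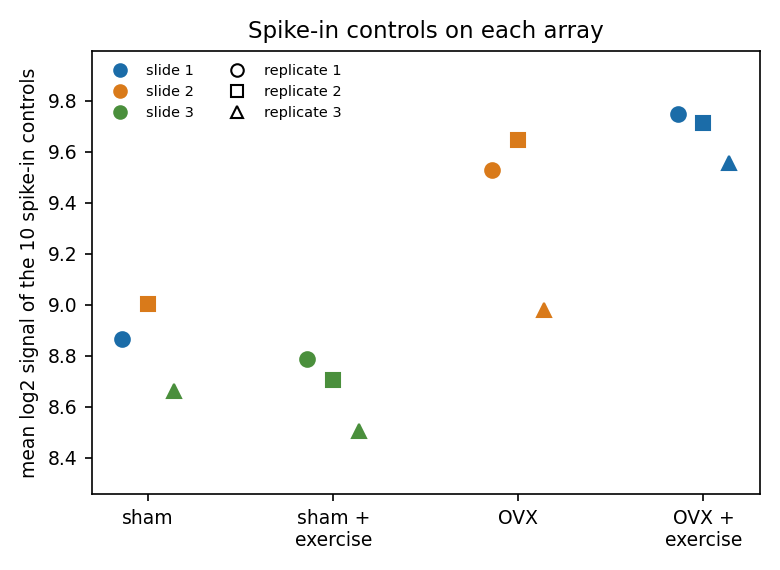
Mean log2 signal of the 10 spike-in controls on each array, by group on the horizontal axis, with the colour giving the slide and the symbol the replicate. The 5 brighter arrays lie between 9.53 and 9.75 and the 7 dimmer ones between 8.51 and 9.00, with ovariectomized replicate 3 among the dimmer.

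The first comparison asked what ovariectomy changed in bone of mice that did not exercise. The RNA NONMMUT019941, which has no gene name in the tables used, rose by 3.69 ± 0.29 (SE, log2), from -3.79 ± 0.73 in sham to -0.10 ± 0.12 in ovariectomized bone (SD, n = 3 each). The non-coding transcript XR_874398.1 fell by 2.47 ± 0.28, being well above background on 1 ovariectomized array and on all 3 sham arrays. No named gene passed. Among named genes with the smallest p, Gm10248, which overlaps Lrmda, was at least 4.01-fold higher (2.00 ± 0.30, adjusted p = 0.0796), being well above background on all 3 ovariectomized arrays and on no sham array. Gm39868, which overlaps Prg3 and lies next to Prg2, the gene of the eosinophil major basic protein, differed by 1.34 ± 0.20 (adjusted p = 0.0796). Gm35787 differed by 0.80 ± 0.16, C130060C02Rik by 1.13 ± 0.24 (at least 2.18-fold, well above background on 2 ovariectomized arrays and no sham array) and Gm15499 by 0.58 ± 0.12, with adjusted p of 0.151, 0.157 and 0.159. On the lower side, Ifngas1, the antisense RNA beside the interferon gamma gene Ifng, differed by -1.15 ± 0.20 (adjusted p = 0.116). Gm35469, which overlaps the corticotropin-releasing hormone receptor gene Crhr1, differed by -1.51 ± 0.29, Gm34613 by -0.97 ± 0.20, Gm29674 by -0.80 ± 0.17 and C030023E24Rik by -2.03 ± 0.44, with adjusted p of 0.140 to 0.163. Gm35469 and C030023E24Rik were well above background on no ovariectomized array, and their falls are given as at least 2.85-fold and 3.76-fold.

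By limma, 9 of 80713 probes passed for the operation in non-exercised mice, 8 higher and 1 lower, and 9796 had an unadjusted p under 0.05. All 3 ovariectomized arrays and only sham replicate 2 share a slide. Within it the difference was 4.47 for NONMMUT019941, -2.65 for XR_874398.1, 2.05 for Gm10248 and -1.02 for Ifngas1. As blocks, slide left 2 probes and spike-in brightness 14, of which 2 in each case were among the 9. The count was 1004 without sham exercised replicate 1, 266 without sham replicate 2, 27 without ovariectomized exercised replicate 2, and 2 or 3 without any 1 of ovariectomized replicates 1 to 3, ovariectomized exercised replicates 1 and 3, and sham replicates 1 and 3.

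In exercised mice, the same operation was compared on a background of training. Here 54 named genes rose and none fell, of which 51 are long non-coding RNAs, 2 are protein-coding (Unc80 and Ccdc117) and 1 is a transcribed pseudogene (Ppp1r2-ps7). Gm38996 rose the most among named genes picked by the rule, 16.1-fold. It went from -4.50 ± 0.37 in sham exercised to -0.49 ± 0.96 in ovariectomized exercised bone (SD, n = 3 each). The log2 difference was 4.01 ± 0.53 (SE, adjusted p = 0.0210). Gm34644, next to the GABA receptor gene Gabrb2, rose 9.27-fold (3.21 ± 0.55). Gm33669, next to the lamin B receptor gene Lbr, rose 4.38-fold, from 0.93 ± 0.04 to 3.06 ± 0.46 (2.13 ± 0.31). Gm34048, which overlaps Gpr149, rose at least 5.64-fold, Gm33867 at least 4.39-fold and Gm38934 at least 4.24-fold, each well above background on no sham exercised array. Gm33861, which lies next to Dyrk2, rose by 1.91 ± 0.33, while its dimmer probe differed by 0.80.

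On the lower side no named gene passed after ovariectomy in exercised mice. Ifngas1 came closest, at -1.02 ± 0.20 (adjusted p = 0.0503). Pisd-ps3, a transcribed pseudogene, differed by -1.32 ± 0.26 (adjusted p = 0.0519), Gm36572 by -0.81 ± 0.19, the T cell receptor segment Trav13-5 by -1.28 ± 0.32, and Gm39383 by -0.91 ± 0.23, at least 1.88-fold lower, being well above background on 2 sham exercised arrays only. NONMMUT019941 rose again, by 3.81 ± 0.29, and XR_874398.1 fell by 2.27 ± 0.28, again well above background on 1 of the 3 ovariectomized exercised arrays, and did not pass with slide as a block.

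In all, 512 probes passed for the operation in exercised mice, 494 higher and 18 lower, and 17507 had an unadjusted p under 0.05. RefSeq non-coding transcripts made up 23.3% of the probes that rose and 11.8% of those tested (Fisher's exact test, two-sided, p = 6.17e-13; probes are not independent). NONCODE transcripts made up 35.0% against 28.5% (p = 0.00163, same exact test), and probes of Agilent's catalogue 26.9% against 42.5% (p = 6.89e-13, same exact test). Probes that rose were dim, with a median mean level of -3.70 against -1.45 for all tested. The exact tests were not matched for level, so the shares of the probe kinds were not separated from it. Called or not, the 8072 dimmest probes tested differed by a median of 0.42 and the 8072 brightest by -0.06, which quantile normalization brought to 0.09 and 0.0030. The 2 groups share no slide. Against the sham array on its own slide, Gm38996 differed by 3.00 in ovariectomized exercised, 2.03 in ovariectomized and -0.33 in sham exercised bone, and Gm33669 by 1.73, 1.44 and 0.18. Gm33867 differed little there, by 0.10 and 0.13, against -1.14 in sham exercised bone. Once slide entered as a block, Gm38996 differed by 3.33 ± 1.16 and Gm33669 by 1.55 ± 0.65, and none of the 7 named genes passed. In all 6 probes passed with that block, with spike-in brightness as a block 4, and with quantile normalization 36, when none of the 7 genes passed (adjusted p from 0.0501 to 0.107). With spike-in brightness as a block the 494 higher probes had a median of 1.14 with a median SE of 0.42, against 1.41 and 0.23 without a block.

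The count for the operation in exercised mice also moved with single arrays. It was 4 without ovariectomized exercised replicate 1 or replicate 2, 51 without its replicate 3, 152, 54 and 71 without sham exercised replicates 1, 2 and 3, and 63 and 272 without ovariectomized replicates 2 and 3. Without sham replicates 1, 2 and 3 it was 2841, 79 and 2987. None of the 7 named genes passed without ovariectomized exercised replicate 1, without its replicate 2 or without sham exercised replicate 2, and 2 of the 7 passed without any 1 of ovariectomized exercised replicate 3, ovariectomized replicate 2, sham exercised replicates 1 and 3, and sham replicate 2.

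**Figure D2:**
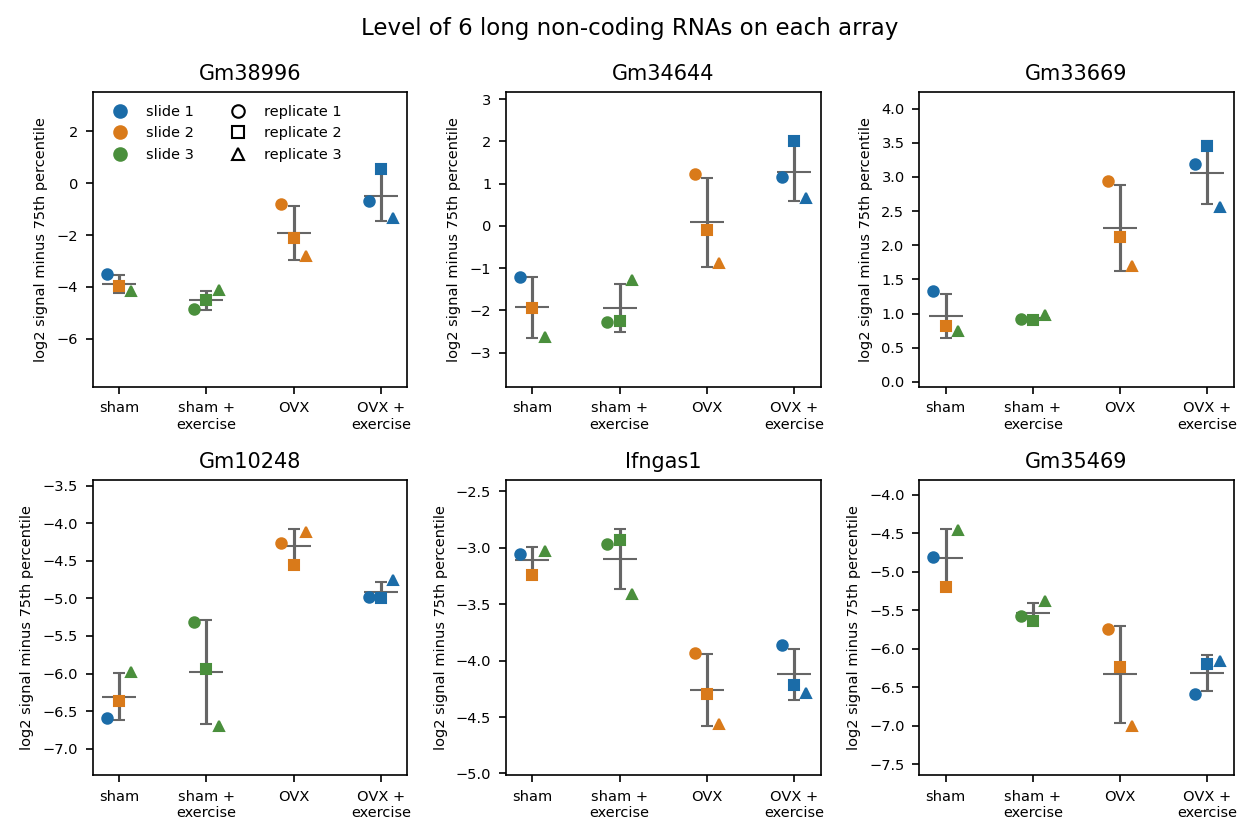
Level of 6 long non-coding RNAs on each array (vertical axes, log2 signal minus the array's 75th percentile) by group, with horizontal bars for the group mean, vertical bars for ± 1 SD (n = 3), colours for the slide and symbols for the replicate. Gm38996 lies at -4.50 in sham exercised and -0.49 in ovariectomized exercised bone on average, and Ifngas1 at -3.10 and -4.12.

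Averaged over exercise, 46 named genes were higher and 4 lower in ovariectomized than in sham bone. Gm38996 rose 7.91-fold (2.98 ± 0.38, SE; adjusted p = 0.0103), Gm34644 6.11-fold (2.61 ± 0.39) and Gm33669 3.27-fold (1.71 ± 0.22), while Gm34048 rose at least 4.17-fold and Gm38934 at least 3.26-fold, each well above background on 5 of 6 ovariectomized and 0 of 6 sham arrays. Ifngas1 fell by 1.09 ± 0.14, from -3.11 ± 0.18 in the sham arrays to -4.19 ± 0.26 in the ovariectomized arrays (SD, n = 6 each; adjusted p = 0.0117), without overlap between them. Gm35469 fell at least 2.21-fold, well above background on 5 of 6 sham and 0 of 6 ovariectomized arrays. Pisd-ps3 fell by 1.02 ± 0.18 and Gm36572 by 0.77 ± 0.13, the latter with overlapping arrays. Against the sham array of the same slide, Ifngas1 differed by -1.06 in ovariectomized exercised, -1.02 in ovariectomized and -0.07 in sham exercised bone. NONMMUT019941 rose by 3.75 ± 0.20 (adjusted p = 6.08e-05). The catalogue probe A_66_P104296 rose by 2.80 ± 0.11 (adjusted p = 4.86e-06), and A_51_P450788 fell by 2.18 ± 0.25. Both catalogue probes were chosen after their values were seen. Neither A_51_P450788 nor XR_874398.1 passed with either block, the adjusted p being 0.643 and 0.401 with the slide. With spike-in brightness as a block A_51_P450788 differed by -1.39 ± 0.45, and ovariectomized replicate 3, at -0.14, lay among the sham arrays (-0.16 to 1.85).

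For the averaged operation effect 773 probes passed, 581 higher and 192 lower, among them the 9 that passed in non-exercised mice and 302 of those that passed in exercised mice. The simple comparisons, which share no array, had 6 called probes in common, all in the same direction, where independent lists would share 0.0571. The lists are not independent, since 1 fit gave both comparisons the same spread for a probe. Both comparisons also follow the split of the spike-in controls, so 0.0571 is not a no-change value. An unadjusted p under 0.05 was found for 19975. The slide block left 4 probes and none of the 9 named genes, Gm38996 being 2.68 ± 0.71 and Gm33669 1.49 ± 0.40, and none of the 9 changed sign. With spike-in brightness as a block 15 passed and again none of the 9. The 581 higher probes then had a median of 0.78 with a median SE of 0.34, against 0.97 and 0.17 without a block. Higher probes made up 75.2% of the 773, while quantile normalization gave 363 higher and 225 lower and normexp 429 higher and 555 lower. NONMMUT019941 and A_66_P104296 passed under each of these blocks, at 4.41 ± 0.18 and 2.70 ± 0.20 with the slide and at 3.87 ± 0.43 and 2.94 ± 0.24 with the spike-in brightness. NONMMUT019943 and NONMMUT019942, whose IDs adjoin that of NONMMUT019941, rose by 3.35 ± 0.21 and 2.43 ± 0.22 without a block and passed with neither block. Whether they share a locus was not tested. The count was 106, 121 and 318 without ovariectomized exercised replicates 1, 2 and 3, 173, 91 and 350 without ovariectomized replicates 1, 2 and 3, 227 without sham exercised replicate 2, and 8562 and 155 without sham replicates 1 and 3. Between 5 and 9 of the 9 named genes passed with any 1 array left out.

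**Figure D3:**
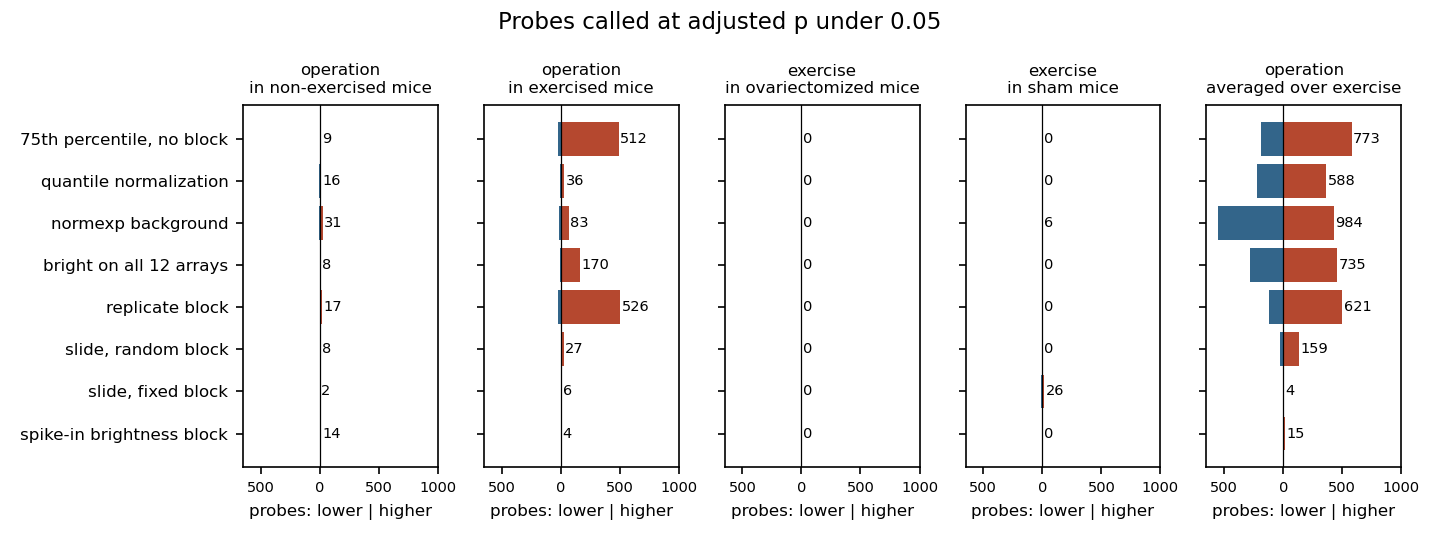
Number of probes at an adjusted p under 0.05 (horizontal axes, lower to the left of 0 and higher to the right, total beside each bar) for 5 comparisons under 8 settings. The averaged operation effect had 773 probes without a block, 4 with slide as a fixed block and 15 with spike-in brightness as a block, and exercise in ovariectomized mice had 0 in each setting shown.

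Of 33 known long non-coding RNAs fixed as a list, 12 were measured under their name. None passed for the operation over all probes. After the operation in exercised mice 8 of the 12 were lower and 4 higher, with a median of -0.06, and camera placed the list below the other named genes (adjusted p = 0.0167 over the 7 comparisons). The averaged operation effect gave a median of -0.07 (adjusted p = 0.0147), and non-exercised mice -0.09 (adjusted p = 0.0840; unadjusted 0.0360). With an estimated correlation none passed, the adjusted p being 0.0732, 0.0732 and 0.153, and fry, which tests whether the members move 1 way, gave unadjusted values of 0.779, 0.199 and 0.161. When slide was a block, the unadjusted camera p was 0.616, 0.173 and 0.130, and with spike-in brightness as a block 0.123, 0.115 and 0.264. Without the filter on dim probes it was 0.141, 0.0955 and 0.180. For the exercise comparisons in ovariectomized and in sham mice camera gave 0.502 and 0.444, with a direction opposite to the medians of 0.06 and -0.05. Kcnq1ot1, the imprinted RNA that runs antisense through Kcnq1, was 1.68-fold higher in ovariectomized exercised than in sham exercised bone (0.75 ± 0.17). After the operation in non-exercised mice it differed by 0.02 ± 0.17. In exercised mice it passed adjusted over the list alone (adjusted p = 0.0152) and not over all probes (0.0717). Its level was -2.31 ± 0.04 in sham exercised and -1.57 ± 0.27 in ovariectomized exercised bone (SD, n = 3 each), and with slide as a block the difference was 0.45 ± 0.33. Airn, the imprinted RNA that overlaps Igf2r, differed by -0.74 ± 0.25 in non-exercised and -0.41 ± 0.25 in exercised mice, the latter turning to 0.33 with slide as a block. Firre differed by -0.43 ± 0.27 and -0.60 ± 0.27, and Hottip, which lies next to Hoxa13, by 0.90 ± 0.42 and 0.67 ± 0.42, the latter turning to -1.03 with slide as a block. Meg3, next to Dlk1, differed by -0.14 ± 0.26 and -0.06 ± 0.26, and Neat1, the scaffold of paraspeckles, by -0.25 ± 0.27 and 0.17 ± 0.27, turning to 0.16 with spike-in brightness as a block and to -0.081 with quantile normalization.

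Bone, marrow and metabolic genes could be named only through single transcripts, and none of those named passed over all probes in any comparison. Other genes of these lists may be among the 34327 tested catalogue probes, which have no name here, so nothing is known of them. For the estrogen receptor beta gene Esr2, a probe of its non-coding transcript differed by 0.35 ± 0.14 after the operation in non-exercised and 0.43 ± 0.14 in exercised mice (adjusted p = 0.337 and 0.127). Of 2 measured members of the estrogen list 1, Esr2, passed adjusted over the list alone in exercised mice and for the averaged effect of 0.39 ± 0.10. In exercised mice Esr2 differed by 0.31 ± 0.28 with slide and 0.31 ± 0.26 with spike-in brightness as a block, where its unadjusted limma p was 0.301 and 0.259. Igf1, a growth factor of bone and the other measured member, differed by -0.60 ± 0.41 and -0.65 ± 0.41, the latter turning to 0.10 with slide as a block. The chondrocyte collagen gene Col11a1 differed by -2.27 ± 0.57 in non-exercised and 0.06 ± 0.57 in exercised mice, with an interaction of 2.33 ± 0.80 that did not pass over all probes (adjusted p = 0.508). The stromal chemokine gene Cxcl14 differed by -1.42 ± 0.46 and -1.04 ± 0.46, and the neutrophil gene Itgb2l by 0.90 ± 0.36 averaged over exercise, with an interaction of -1.21 ± 0.72 that turned to 0.98 ± 0.84 with slide as a block. Each of these 3 genes is the 1 measured member of its list, so a p adjusted over the list alone is the unadjusted p. For the operation in non-exercised mice it was 0.00212 for Col11a1, 0.0103 for Cxcl14 and 0.0137 for Itgb2l, against 0.194, 0.269 and 0.288 adjusted over all probes. It was also under 0.05 for each averaged operation effect, for Cxcl14 in exercised mice, and for Col11a1 for exercise in sham mice (-1.32 ± 0.57) and for the interaction. Cxcl14 in exercised mice lost this with either block, at -0.70 ± 1.01 with slide and -0.56 ± 0.85 with spike-in brightness. Col11a1 for exercise in sham mice lost it with slide (-1.64 ± 0.84) and kept it with spike-in brightness, while its interaction kept it with either. With slide as a block, the operation in non-exercised mice gave 0.37 ± 0.20 for Esr2, -2.60 ± 0.84 for Col11a1, -1.58 ± 0.72 for Cxcl14 and 0.27 ± 0.48 for Itgb2l, and of these only Col11a1 had an unadjusted p under 0.05. With spike-in brightness as a block the values were 0.27 ± 0.20, -1.03 ± 0.63, -1.10 ± 0.67 and 1.67 ± 0.76, none of them under 0.05. The averaged operation effect lost its unadjusted p under 0.05 with either block for each of Esr2, Col11a1, Cxcl14 and Itgb2l, and that of Col11a1 turned from -1.10 ± 0.40 to 0.44 ± 0.64 with spike-in brightness as a block. With that block Col11a1 differed by 1.91 ± 0.81 for the operation in exercised mice and by 2.94 ± 0.67 for the interaction, both with an unadjusted p under 0.05. After the operation in non-exercised mice the remaining members gave 0.02 ± 0.15 for Cs, 0.07 ± 0.18 for Mx2, -0.33 ± 0.20 for Sod1, -0.08 ± 0.37 for Cry2, -0.16 ± 0.25 for Atg12, -0.18 ± 0.26 for Ctsl and -0.72 ± 0.36 for Ulk2. Those of Cry2, Atg12 and Ctsl turned to 0.031, 0.30 and 0.13 with slide as a block, and that of Mx2 to -0.092 with spike-in brightness as a block. With the latter block Sod1 differed by -0.65 ± 0.26, with an unadjusted p under 0.05, Cs by 0.33 ± 0.18 and Ulk2 by -0.16 ± 0.47.

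Exercise in ovariectomized mice, the comparison closest to the title of the series, gave no probe that passed. Among named genes, Gm39067, next to Eif3f, differed by 1.08 ± 0.17 (SE), from -4.97 ± 0.33 in ovariectomized to -3.89 ± 0.11 in ovariectomized exercised bone (SD, n = 3 each). Gm42318, next to the matrilin gene Matn1, was at least 1.90-fold higher and the odorant receptor gene Olfr78 differed by 1.42 ± 0.31. F930026P19Rik differed by 0.77 ± 0.20 and Gm39203 by 0.64 ± 0.17. Lower values were -0.89 ± 0.19 for Rttn, a gene of centriole assembly, -0.79 ± 0.18 for Gm42225, -0.65 ± 0.15 for 9130209A04Rik, -0.85 ± 0.23 for Gm33377 and -0.93 ± 0.25 for Gm8075, which lies between Prkch and Hif1a. The adjusted p of each of these 10 genes was 0.746. Neat1 differed by 0.71 ± 0.27 with the same adjusted p, Meg3 by 0.16 ± 0.26, Esr2 by 0.09 ± 0.14 and Igf1 by 0.10 ± 0.41. By limma 0 probes passed and 5357 had an unadjusted p under 0.05. The count stayed at 0 in each alternative, slide and spike-in brightness as blocks included, except at an unadjusted p under 0.05 with a 2-fold change, which 595 probes met. These groups share no slide, and with slide as a block Gm39067 differed by 0.92 ± 0.35.

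Exercise in sham mice likewise gave 0 probes by limma, with 9409 at an unadjusted p under 0.05. Acpp, an acid phosphatase gene, differed by 1.14 ± 0.22, 4930431F12Rik by 1.28 ± 0.25, the lymphocyte kinase gene Stk17b by 0.82 ± 0.17 and Gm30489, which overlaps the factor XIII gene F13a1, by 0.99 ± 0.22. The brighter probe of 1500009C09Rik was at least 1.61-fold higher (well above background on 2 sham exercised arrays and no sham array), while its dimmer probe differed by -1.51. Gm32829 was at least 2.50-fold lower (well above background on no sham exercised and 2 sham arrays), and Gm35326 differed by -0.95 ± 0.16, Gm39697 by -0.76 ± 0.13, D830015G05Rik, which overlaps Pex5 and lies next to the macrophage receptor gene Cd163, by -1.22 ± 0.22, and Gm41519 by -0.98 ± 0.18. Their adjusted p lay between 0.102 and 0.167. Kcnq1ot1 differed by -0.80 ± 0.17, past the threshold adjusted over the list alone (adjusted p = 0.00915) and not over all probes (0.163). The same sham exercised arrays enter its difference after the operation in exercised mice, so both passes rest on them (exercise in ovariectomized mice gave -0.08 ± 0.17). Neat1 differed by 0.28 ± 0.27, Meg3 by 0.07 ± 0.26 and Esr2 by 0.02 ± 0.14. Igf1 differed by 0.16 ± 0.41 and by -0.22 with slide as a block. All sham exercised arrays and only sham replicate 3 share a slide, where Acpp differed by 1.66, Gm32829 by -1.14 and Kcnq1ot1 by -0.75. The slide block gave 26 probes, 16 higher and 10 lower, but none of these 10 genes, spike-in brightness as a block gave 0, and normexp gave 6. Without sham exercised replicate 1 the count was 93, without sham replicate 2 it was 223 and without sham replicate 3 it was 28.

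Averaged over the operation, exercise gave 0 probes by limma, with 7831 at an unadjusted p under 0.05. Values were 0.54 ± 0.11 for 6330407A03Rik, which overlaps the kinase gene Lyn, 0.53 ± 0.11 for 1500009C09Rik, 0.43 ± 0.09 for 4930439A04Rik, -0.96 ± 0.16 for Gm38752, next to Hmgb1 and well above background on 1 of 6 exercised and 5 of 6 other arrays, -0.85 ± 0.16 for 4930455C13Rik, between Myb and Aldh8a1, and -0.66 ± 0.12 for Gm41519. The adjusted p was 0.238 to 0.268. The slide block gave 11 probes, 8 higher and 3 lower, and spike-in brightness as a block gave 0. Without sham replicate 2 the count was 15 and without sham replicate 3 it was 1.

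Whether exercise acted differently after ovariectomy was tested by the interaction, for which 0 probes passed and 7203 had an unadjusted p under 0.05. Gm32829, next to Usp27x, had an interaction of at least 1.66, being well above background on no sham exercised array, Gm39697 of 1.08 ± 0.19 and Gm30762 of 1.24 ± 0.23. It was -0.96 ± 0.19 for Gm41461, which overlaps the adhesion gene Alcam, -1.14 ± 0.29 for Gm39868 and -1.13 ± 0.30 for Os9. Their adjusted p was 0.384 to 0.456. The higher number of probes that passed for the operation in exercised than in non-exercised mice was therefore not matched by a tested difference. In simulated data this test recovered 0% of 2-fold and 47% of 4-fold changes, so it does not show that the operation acted alike. Of the 512 probes, 412 lay in the same direction in non-exercised mice. The 2 operation effects correlated at 0.388 over all probes, and the share of all probes with the same direction was not computed. The interaction test passed 1 probe with slide and 0 with spike-in brightness as a block. Without sham replicate 2 the count was 20 and without sham replicate 3 it was 1.

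The last comparison asked whether exercise moved RNAs against their difference after ovariectomy. No probe passed in both comparisons with opposite signs. Of 926 probes with an unadjusted p under 0.05 for the operation and for exercise in ovariectomized mice, 734 had opposite signs. Both comparisons use the same ovariectomized arrays, which alone gives opposed values. The correlation across probes was -0.210, against -0.500 in simulated groups without any change, and the covariance was -0.0269 against -0.0409, a difference of 0.0140. With slide as a block the correlation was -0.556, against -0.707 in groups without any change simulated in that design. With spike-in brightness as a block it was -0.229 against 0.000697, so that it lay on the other side of its simulated value, and the covariance was -0.0302 against 9.12e-05. The simulated noise was independent between probes and between arrays, with no slide, spike-in or brightness difference. The simulated values therefore need not hold for the real arrays, and the comparison does not decide whether exercise opposed the operation. Without a block, the correlation was -0.307 without ovariectomized replicate 3, -0.0193 without sham replicate 1 and -0.358 without sham replicate 3. The effects of exercise in ovariectomized and in sham mice, which share no array, correlated at 0.0669 across probes, at 0.253 without sham replicate 1, at -0.0689 without sham replicate 3 and at -0.0470 without sham exercised replicate 1.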

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

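The tests of the slide, the brightness dependence and the spike-in batch were chosen only after the results were seen. Spike-in controls, which no comparison uses, differed between arrays. Of 10 controls, 6 did not overlap between the 5 brighter and the 7 dimmer arrays. The brighter arrays were higher by 0.57 for control 1, 1.35 for a135, 0.58 for a22, 1.75 for a97, 1.46 for n11 and 1.12 for n9, on the log2 scale. The brighter arrays are all 3 ovariectomized exercised arrays and ovariectomized replicates 1 and 2, so the split follows the operation except for ovariectomized replicate 3.

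Probes that passed for the operation in exercised mice were mostly dim and higher. An intensity-dependent shift left by the percentile scaling stays open: these 494 probes had a median difference of 1.41 before and 1.14 after quantile normalization, with a median SE of 0.23 and 0.22, while the median of the 8072 dimmest probes tested went from 0.42 to 0.09. The calls fell there from 512 to 36, as the differences shrank while the SE stayed near its size, and normexp, whose offset shrinks the differences of dim probes, took the median to 0.32 with an SE of 0.12. A difference between slides may account for part: with the slide as a block the median was 0.85, with an SE of 0.40 in place of 0.23, so part of the lost calls is lost precision. On a scale from sham exercised at 0 to ovariectomized exercised at 1, the sham arrays followed the slides over these probes. Their median positions were 0.65 on slide 1, 0.48 on slide 2 and 0.23 on slide 3, with 1 array each. On slide 2 the ovariectomized arrays lay higher than its sham array, at 0.58 to 0.79. The slide and the operation cannot be told apart here, since the 2 groups share no slide and the link rests on 1 sham array per slide, and an effect of ovariectomy stays open.

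The averaged operation effect raises the same question. With the slide as a block, the 581 probes that rose had a median of 0.69 against 0.97 without it. A labelling batch seen in the spike-in controls would put ovariectomized replicate 3, the only dim one of its operation, with the sham arrays. On a scale with sham at 0 and the other ovariectomized arrays at 1, its median position was 0.48 over 289 probes that rose in the fit without it, and 0.69 over 61 that fell. A position between the groups leaves both a labelling batch and the operation open, which this single array cannot tell apart.

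A few unnamed probes passed whichever block was used. Of the 773 probes of the averaged operation effect, 3 passed with the slide as a block and 4 with spike-in brightness as a block, counts that decide nothing by themselves since these probes were picked for passing. For A_66_P104296 and NONMMUT019941, which had the smallest p without any block, a slide difference is argued against as the whole cause. With the slide as a block they differed by 2.70 ± 0.20 and 4.41 ± 0.18 (SE), against 2.80 and 3.75 without it, and passed over all probes. The choice by smallest p favours probes that are alike on the sham arrays of the 3 slides. The block links the groups through sham arrays at position 4, so array position stays in these values. A labelling batch would put ovariectomized replicate 3 with the sham arrays. On the scale from sham at 0 to the other ovariectomized arrays at 1 it lay at 1.06 and 1.04. This decides nothing, since the 2 probes were picked by a fit that held this array, which favours such a position. It is also a single array, as is the basis of the spike-in block. Both may respond to ovariectomy, as a hypothesis found and tested on the same data, with a labelling batch and the array position still open.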

How the results depend on the processing

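The slide as a random block, spike-in brightness as a block and quantile normalization with the slide block were chosen only after the results were seen. Counts are of probes at an adjusted p under 0.05, in the order operation in non-exercised mice, operation in exercised mice and averaged operation effect, which were 9, 512 and 773. They were 16, 36 and 588 with quantile normalization, 31, 83 and 984 with normexp, 11, 337 and 537 without a filter on dim probes, and 8, 170 and 735 for probes well above background on all 12 arrays. They were 28, 148 and 804 with an intensity trend and robust moderation, 9, 502 and 773 with the deposited log2 values, 11002, 15737 and 23144 with array quality weights (0.143 for sham exercised replicate 1 to 5.48 for sham replicate 2), and 1957, 2785 and 1129 at an unadjusted p under 0.05 with a 2-fold change. With the slide as a block they were 2, 6 and 4, as a random block 8, 27 and 159, with quantile normalization and the slide block 2, 5 and 4, and with spike-in brightness as a block 14, 4 and 15. With only the 2 groups compared they were 7 and 182. The averaged effect had 581 higher and 192 lower probes, 429 and 555 with normexp and 363 and 225 with quantile normalization. The cause of these changes was not tested, except that the slide block leaves 6 of 8 residual degrees of freedom. Array quality weights of sham replicates 1 and 3 were 0.337 and 0.485, against 5.48 for sham replicate 2. Weighted comparisons with the sham group, exercise in sham mice included, therefore rest mostly on that 1 sham array.

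The exercise comparisons had 0 probes. Exercise in sham mice gave 6 with normexp, 26 with the slide block, 55 with quantile normalization and the slide block, 12320 with array quality weights, 1 with trend and robust moderation, and 1445 at an unadjusted p with a 2-fold change. The interaction gave 1, 1, 2832 and 2382 with the slide block, with quantile normalization and the slide block, with weights and at an unadjusted p with a 2-fold change. The averaged exercise effect gave 11, 18, 3444 and 230 in the same order, and exercise in ovariectomized mice gave 595 at an unadjusted p with a 2-fold change and 0 otherwise. At an unadjusted p under 0.05 the known long non-coding RNAs passed camera in 3 comparisons, in 2 with an estimated correlation or with normexp, and in 0 with fry, without the filter, with the slide block or with spike-in brightness as a block. The correlation of the opposed changes was -0.556 with the slide block, where groups simulated without any change and with independent noise gave -0.707.

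Leaving out 1 array gave 2 to 1004 probes for the operation in non-exercised mice, 4 to 2987 in exercised mice, 91 to 8562 averaged, 0 to 223 for exercise in sham mice, 0 to 20 for the interaction, 0 to 15 for the averaged exercise effect, 0 for exercise in ovariectomized mice, and 2 to 3 comparisons for the gene list. The correlation of opposed changes ranged from -0.358 to -0.0193, for which no no-change values were simulated. That of the exercise effects ranged from -0.0689 to 0.253, below 0 without sham replicate 3 or without sham exercised replicate 1.

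The replicate block gave 17, 526 and 621 probes for the operation in non-exercised mice, in exercised mice and averaged, and 0 for each exercise comparison and the interaction. Deviations of the 18 same-numbered pairs correlated at 0.0466 on average (-0.284 to 0.312, 7 of them over 0.1). Those of the 36 other pairs correlated at -0.0242 (9 of them over 0.1). Deviations sum to 0 within a group, which ties the mean of the other pairs to that of the same-numbered ones. These means therefore do not decide whether the numbers pair the samples.

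Among values of genes picked by the rule, those that changed sign, none of which had passed, were for the operation in non-exercised mice Neat1 0.16 with spike-in brightness as a block. For the operation in exercised mice they were Igf1 0.10 with the slide block and 0.076 with quantile normalization and the slide block, Airn 0.33 and 0.30 in the same order, Meg3 0.20 with weights, and Neat1 -0.081 with quantile normalization and -0.048 with normexp. For exercise in sham mice they were Igf1 -0.22 with the slide block, -0.26 with weights and -0.20 with quantile normalization and the slide block, Meg3 -0.32 with weights, and Esr2 -0.056 with quantile normalization and -0.0078 with normexp. With 1 array left out, values that took both signs ranged for the operation in non-exercised mice from -0.38 to 0.0093 (Meg3) and -0.46 to 0.029 (Neat1), in exercised mice from -0.31 to 0.17 (Meg3) and -0.045 to 0.36 (Neat1), for exercise in ovariectomized mice from -0.090 to 0.24 (Igf1), and for exercise in sham mice from -0.39 to 0.54 (Igf1), -0.034 to 0.051 (Esr2) and -0.17 to 0.32 (Meg3). List genes outside the rule changed sign too, in 4 of 17 values for the operation in non-exercised mice and 9 of 17 in exercised mice with the slide block, and in 4 of 17 in each with spike-in brightness as a block. Of their values given in the report, these also turned with another setting: Cry2 (0.033), Atg12 (0.34) and Ctsl (0.16) for the operation in non-exercised mice with quantile normalization and the slide block, all 3 with weights, Cs (-0.0025) with normexp, for the operation in exercised mice Col11a1 (-0.21) with quantile normalization and Hottip (-0.90) with that and the slide block, and the interaction of Itgb2l (1.13) with both. With 1 array left out Cs, Atg12 and Mx2 in non-exercised and Col11a1 in exercised mice took both signs. Signal over background limits the dim probes, since 66191 of the 80713 tested were well above background on all 12 arrays.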

Other observations

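The tests of other splits of the samples were chosen only after the results were seen, while the sets of neighbouring genes were fixed before theirs. The probes of the averaged operation effect that depended on no single array numbered 83, of which 72 were higher, 11 lower and 7 from named genes. Of these, 64 also passed with quantile normalization and with normexp. Of the 64, 3 also passed with the slide as a block, 3 with spike-in brightness as a block and 2 with each of these, and 0 of these have a gene name. Probes of Agilent's catalogue, a source of probes without a gene name here, made up 61.5% of the 192 lower, 29.3% of the 581 higher and 42.5% of the tested probes (Fisher's exact test against those tested, two-sided, p = 1.55e-07 for lower and p = 3.94e-11 for higher ones; probes are not independent). Lower and higher probes were not tested against each other, and the tests were not matched for signal level.

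One hypothesis was that non-coding RNAs follow the list genes they overlap or adjoin. In 26 sets of such neighbours, tested by camera with an estimated correlation in 104 set and comparison pairs, 0 passed, with a smallest adjusted p of 0.988, and 0 passed with the preset correlation. This does not decide the hypothesis, since only 24 of the 662 list genes were measured under their name, and the change that their neighbours would follow is unknown.

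Other splits of the same arrays were fitted, for the averaged operation effect within exercised and within non-exercised arrays and for the averaged exercise effect within each operation. For the averaged operation effect only the real split of 100 gave as many probes as 773, the highest other giving 242. This argues against a random grouping, though not against the slide or the labelling batch, which the real split follows in part. Other splits put such differences into the spread, which lowers their counts. For the interaction 16 of 100 splits gave at least the 7203 probes at an unadjusted p under 0.05, with a highest other of 19333, and for the averaged exercise effect 13 of 100 gave at least 7831, with a highest other of 15662, so a random grouping cannot be excluded for either.

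With 3 arrays against 3 there are 10 splits, too few for a share under 0.05. For the operation in exercised mice 1 split, the real one, gave 512 probes and the highest other gave 1. The real split follows the slides. For the operation in non-exercised mice 2 splits gave at least 9, and ovariectomized replicates 1 and 2 with sham replicate 1 against the rest gave 439, many times the real count, which points to a structure of the samples. For exercise in ovariectomized mice 1 split gave as many as the real 5357 at an unadjusted p under 0.05, the highest other being 3487. For exercise in sham mice 4 splits gave at least 9409, the highest other being 14008.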
